A study of uncultured soil microorganism with 16 samples.

How the data were processed

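DNA from 16 soil samples was measured on GeoChip arrays, which carry oligonucleotide probes for microbial genes of carbon, nitrogen, phosphorus and sulfur cycling and related functions, with 1 sample per array. Per the labels, the mineral soil at a depth of 0 to 10 cm under a planted pine forest was sampled as 5 pooled cores of 5 cm diameter, 0.5 g portions went into DNA extraction with a column kit, and the DNA was labelled by random priming. The labels name the dye as Cy5 in one place and Cy3 in another. The deposited table gives the signal intensity of each probe on a linear scale, and a blank where a probe had no retained signal. The authors appear to have scaled the arrays to a common total, since the deposited intensity sums of the 16 columns differ by less than 2%. The scanner, background correction, detection rule, normalisation method and array version were not given in the sources used here, and the name of the deposited file speaks of outliers left out.

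A probe was called detected on an array when the table held a value for it. The medians of the 26525 probes detected on all 16 arrays spanned 0.32 on the log2 scale, more than the 0.1 that had been fixed as the limit, so the signals were quantile normalised over the detected probes of each array. A missing signal counted as 0 in sums. With this normalisation each array has the same distribution of signals over its own detected probes, so an array with fewer detected probes has a lower sum by construction. Every direction was therefore also computed after total scaling, in which each array is divided by its summed signal. Probes detected on at least 2 of the 4 arrays of at least 1 nitrogen level were kept, 40277 of 42587, and families with at least 3 such probes, 320 of 369.

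The value of a gene family was log2 of its summed probe signals plus 1. Families, single probes (detected on at least 3 of the 4 arrays of both levels compared), gene lists and sums over the source organism of each probe were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 16 arrays, and a separate fit used the nitrogen rate as a number. Adjusted p values are Benjamini-Hochberg values, with a threshold of 0.05, taken per comparison for families and probes and, for list and organism sums, over the 3 comparisons with N0 together or the other comparisons together. Changes are differences of log2 values with the standard error (SE) of the fit and n = 4 arrays per level. The number of probes detected and the Shannon index were compared with two-sided exact permutation tests, for which the smallest p with 4 against 4 arrays is 0.0286, and their slopes on nitrogen rate with a two-sided permutation test. Composition was compared with vegan 2.7.1 (adonis2) by a permutation test of Bray-Curtis distances between levels, exactly over the 35 splits of 8 arrays for pairs of levels. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

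The gene lists were starch, pectin, hemicellulose, cellulose, chitin, lignin, lignin-derived aromatic compounds, protein and lipid degradation (joined as carbon degradation), carbon fixation, methane production, methane oxidation, nitrogen fixation, nitrification, denitrification, dissimilatory and assimilatory nitrogen reduction, ammonification and assimilation, anammox, phosphorus and sulfur, matched by gene name. The lists for the glyoxylate cycle, stress and phylogenetic markers matched 0 genes, and 4 matched symbols were left out because the table uses them for other functions. For each comparison with N0 the named families were up to 10 with the largest rise and 10 with the largest fall among those past the threshold without overlap between the levels, or the 5 with the smallest p in a direction where fewer than 5 passed, and a fixed set of genes of the lists whatever their p. Other named families and probes were chosen after their values were seen. The lists, this rule, the tests and the main alternatives were fixed before the data were examined.

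The alternatives were total scaling, median scaling over the probes detected on all arrays, the values as deposited, other probe filters, other definitions of family and list values, only the compared levels in the fit, missing signals set to the array minimum, other distances, exact tests of list totals, the replicate number as a block, and leaving out each array in turn. Leaving out the pair of arrays with the lowest mean correlation with the others (N6 replicate 4 and N9 replicate 4), also together with total scaling, was added after the data had been seen. The steps were tested on simulated data built for the comparison of N9 with N0. A change of 0.5 on the log2 scale was recovered for 60.6% of changed families when 320 families were tested, and a change of 0.25 for 18.3%. For single probes, a change of 2 was recovered for 53.9% of changed probes when 26525 were tested, and a change of 1 for 2.99%. Unchanged families were called in 10 of 50 simulations and unchanged lists in 8 of 50, with a median of 0 false calls for both. The number of arrays limits the precision. The p values measure only the spread between these samples, since the labels do not say whether replicates were separate plots, and they give no slide, scan date or block.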

Results

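The soils came from a planted forest of Chinese pine (Pinus tabulaeformis) on the Loess Plateau of China that received nitrogen at 4 rates for 5 years. The levels were N0, N3, N6 and N9, at 0, 3, 6 and 9 g of nitrogen per square metre per year, with 4 replicate samples each. The study asks how added nitrogen relates to the breakdown of soil organic carbon and to the microbial genes for carbon degradation. The arrays gave signals for 42587 probes of 369 gene families, of which 36710 were bacterial, 3751 fungal, 1099 archaeal and 506 from other eukaryotes. The summed signal of an array was 136779951 ± 293204 at N0 and 135430477 ± 721135 at N9 (SD, n = 4), and ranged from 134650255 to 137111072 over all arrays.

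Fewer probes gave a signal at the highest rate than at the others. The number detected was 37100 ± 1379 at N0, 38216 ± 1148 at N3, 37114 ± 3071 at N6 and 32914 ± 2396 at N9 (SD, n = 4), or 87.1%, 89.7%, 87.1% and 77.3% of all probes. N9 differed from N0 by -4186 probes (two-sided exact permutation p = 0.0571, adjusted 0.1) and from N3 by -5301 probes (exact p = 0.0286, the smallest possible, adjusted 0.1), and the slope was -455 probes per g of nitrogen (permutation p = 0.0264, adjusted 0.1). N3 differed from N0 by 1116 probes (exact p = 0.2) and N6 from N0 by 13.8 probes (exact p = 1). The latter was -675 without N6 replicate 3 and 1527 without N6 replicate 4. The Shannon index was 9.57 ± 0.037 at N0, 9.59 ± 0.0284 at N3, 9.56 ± 0.0855 at N6 and 9.44 ± 0.0687 at N9, with a difference of -0.122 between N9 and N0 (exact p = 0.0571, adjusted 0.1). None of these differences passed the correction. The index was taken after quantile normalisation, where it largely follows the number of probes detected. Its exact p values for pairs of levels equalled those of the probe numbers, so it is no separate result. As deposited, the index of N0 replicates 1 to 4 was 9.55, 9.49, 9.59 and 9.59. That of N9 replicates 1 to 4 was 9.31, 9.38, 9.49 and 9.56. Probes on all 4 N0 arrays and on 0 of the 4 treated arrays numbered 6 at N3, 6 at N6 and 702 at N9, and the reverse numbered 65, 20 and 10. N6 replicate 4, with 32574 probes, lay among the N9 arrays, and N9 replicate 4, with 36367, among the N0 arrays.

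**Figure D1:**
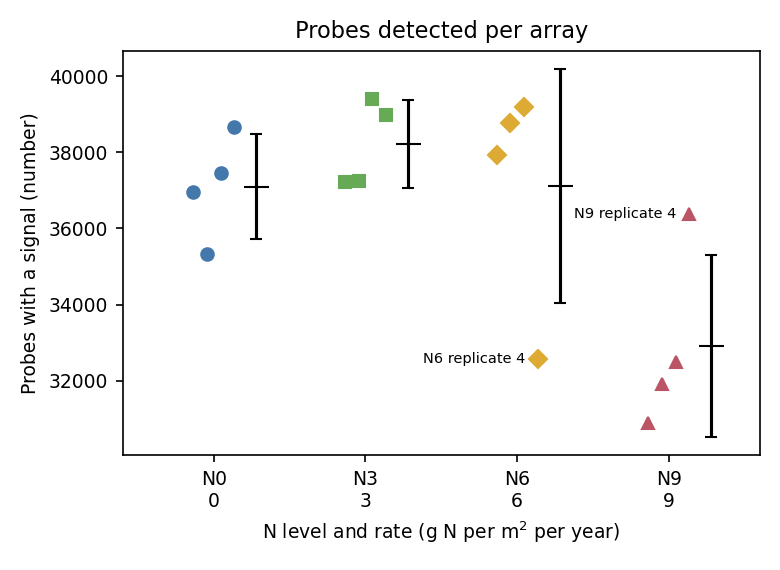
Number of probes with a signal on each of the 16 arrays, by nitrogen level with its rate in g of nitrogen per square metre per year. Points are arrays and the bars beside them give the mean and SD of 4 arrays; 3 of the N9 arrays lie between 30885 and 32490, with N6 replicate 4 at 32574 and N9 replicate 4 at 36367.

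Composition by functional gene signal was compared over all levels. The nitrogen level accounted for 21.2% of the variation of Bray-Curtis distances (permutation test of the distances between levels, p = 0.37). Pairwise shares were 18.0% for N3 against N0 (exact p = 0.171), 11.1% for N6 against N0 (exact p = 0.629), 15.9% for N9 against N0 (exact p = 0.371) and 22.9% for N9 against N3 (exact p = 0.143), and none passed the correction. The mean distance to the level's centroid was 0.0811 at N0, 0.0796 at N3, 0.126 at N6 and 0.177 at N9 (permutation p = 0.146). The test passed the threshold with detection in place of signal (R2 = 0.439, permutation p = 0.01), with log2 signals (R2 = 0.372, permutation p = 0.015) and without N6 replicate 4 and N9 replicate 4 (R2 = 0.363, permutation p = 0.015), where R2 is the share of the variation as a fraction. These arrays had mean correlations of 0.728 and 0.759 with the other 15.

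**Figure D2:**
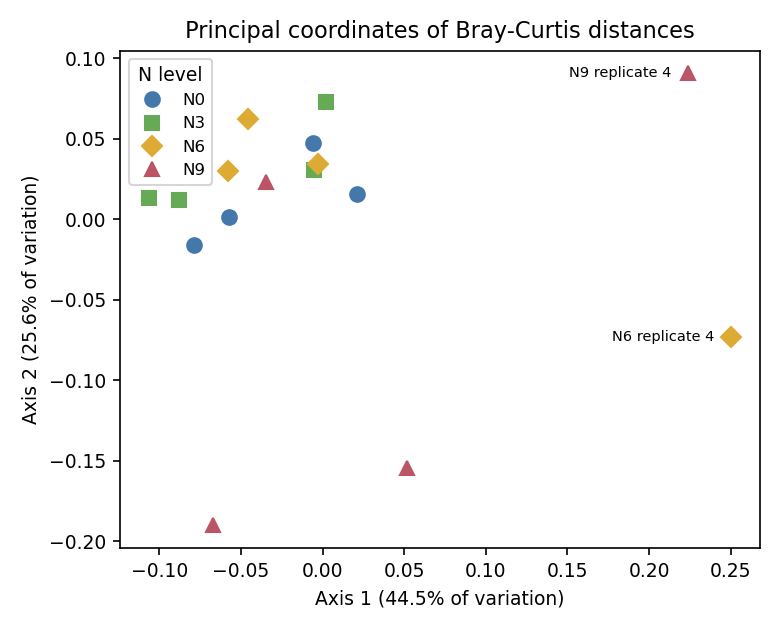
Principal coordinates of Bray-Curtis distances between the 16 arrays, with symbols for the nitrogen levels; axis 1 holds 44.5% and axis 2 holds 25.6% of the variation. N6 replicate 4 and N9 replicate 4 lie apart from the other arrays on axis 1.

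The comparison of N3 with N0 asks what a low rate of nitrogen goes with. Families of carbon degradation lay slightly above N0, as did the median of all families (0.05, or -0.05 under median scaling), but none passed the test. Among the 5 families above N0 with the smallest p were tmoabe, a toluene monooxygenase, at 0.47 (SE 0.16, log2, adjusted p = 0.99, higher on 4 of 4 N3 arrays), and pme_Cdeg, a pectin methylesterase, at 0.24 (SE 0.09, adjusted p = 0.99, 4 of 4). Fungal aspartate proteases stood at 0.31 (SE 0.15), exoglucanase, which cuts cellulose from chain ends, at 0.12 (SE 0.07), and ligninase, a fungal peroxidase acting on lignin, at 0.21 (SE 0.17). In the other direction were nahf, of naphthalene degradation, at -0.29 (SE 0.14) and hzsa, hydrazine synthase of anammox bacteria, at -0.30 (SE 0.21). All 7 kept their direction under total scaling, median scaling and as deposited. Of the 42 carbon degradation families 5 lay below N0, against 17 under total scaling, and 0 passed when adjusted over the list alone.

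In the limma test of N3 against N0, 0 of 320 families passed, by quantile normalisation, total scaling, median scaling or the values as deposited, with 2, 5, 7 and 6 at an unadjusted p under 0.05. The levels did not overlap for 26 families, 8.13% against the 2.86% that chance gives for a single family. They did not overlap for 20 under total scaling and 21 under median scaling. Families are not independent of each other, so these shares are no test. Of the 21 list totals 0 passed (0 at an unadjusted p under 0.05 by either scaling), and carbon degradation as a whole differed by 0.05 (SE 0.07, adjusted p = 0.866). Of the list totals 1 lay below N0, against 9 under total scaling and 20 under median scaling. Of 35378 probes 0 passed (1658 at an unadjusted p under 0.05), against 1 lower under total scaling and 1 without N0 replicate 2, N6 replicate 4, N9 replicate 1 or N9 replicate 2. The signal of fungal probes took 6.29% ± 0.078 of the total at N0 and 6.50% ± 0.056 at N3 (SD, n = 4). The log2 ratio of fungal to bacterial signal, a measure chosen after the data had been seen, was higher by 0.05 at N3 on 4 of 4 arrays (exact p = 0.0286, adjusted 0.429).

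At the middle rate, N6, family signals lay close to N0. Cbaa, a chlorobenzoate dioxygenase, stood at 0.80 (SE 0.33, log2, adjusted p = 0.999, higher on 4 of 4 N6 arrays), and tmoabe at 0.30 (SE 0.16, adjusted p = 0.999, 4 of 4). In the other direction were phta, of phthalate degradation, at -0.25 (SE 0.14) and the fungal glucose oxidase at -0.19 (SE 0.13). Among the carbon genes, exoglucanase stood at 0.06 (SE 0.07) and the manganese peroxidase mnp, which oxidises lignin, at -0.10 (SE 0.14). Of the 42 carbon degradation families 17 lay below N0 (15 under total scaling), and 0 passed when adjusted over the list alone. N6 replicate 4 had the lowest signal of the 4 N6 arrays for mnp (17.19) and for the cellulose list (21.12), on the log2 scale. It also had the fewest probes detected of these, 32574, which lowers such sums after quantile normalisation.

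In the limma test of N6 against N0, 0 of 320 families passed by quantile normalisation, total scaling, median scaling or the values as deposited, with 1, 3, 4 and 3 at an unadjusted p under 0.05. The levels did not overlap for 3 families, 0.938% against the 2.86% that chance gives for a single family, and for 2 under total scaling. Of the list totals 0 of 21 passed (0 at an unadjusted p under 0.05 by either scaling), with changes from -0.09 to 0.06, and carbon degradation as a whole differed by 0.00469 (SE 0.07). That difference was -0.0239 without N6 replicate 3 and 0.0680 without N6 replicate 4. Organism totals gave 0 of 5 (0 at an unadjusted p under 0.05, and 1 under total scaling) for N6 and also for N3 against N0. Of 35581 probes 0 passed (661 at an unadjusted p under 0.05), against 3 lower under total scaling and 3 without N0 replicate 2.

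N9 against N0 compares the highest rate with no addition. The summed signal of most families was lower at N9, with 300 of 320 below 0 and a median family shift of -0.19 after quantile normalisation, which lay near the log2 ratio of detected probes, -0.17. Under total scaling the median shift was -0.02 with 189 families below 0, and under median scaling it was 0.07. The manganese peroxidase mnp stood below the median shift, at -0.39 (SE 0.14, adjusted p = 0.0948, lower on 4 of 4 N9 arrays), or -0.20 relative to it, -0.24 (SE 0.10) under total scaling and -0.15 under median scaling. Phta, also below 0 under every scaling, stood at -0.47 (SE 0.14, adjusted p = 0.0948, 4 of 4), or -0.28 relative to the shift, and pcpA, of chlorophenol degradation, at -0.51 (SE 0.15, adjusted p = 0.0948, 4 of 4), or -0.32 relative to it. Above the shift lay cbaa, at 0.64 (SE 0.33, adjusted p = 0.161, higher on 3 of 4), and tmoabe, at 0.24 (SE 0.16, adjusted p = 0.25, 3 of 4).

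None of the genes named for the main plant and microbial polymers passed the test over all families. For cellulose, endoglucanase stood at -0.22 (SE 0.08) and exoglucanase at -0.22 (SE 0.07, adjusted p = 0.0948 for both, lower on 4 of 4 arrays), or -0.04 and -0.03 relative to the shift, and turned to 0.02 and 0.04 under median scaling. Acetylglucosaminidase, which releases the sugar units of chitin, stood at -0.20 (SE 0.06) and phenol oxidase, a laccase-type enzyme, at -0.22 (SE 0.08), or -0.02 and -0.04 relative to the shift, and turned to 0.06 and 0.04 under median scaling. The starch-degrading amylase gene amyA stood at -0.17 (SE 0.05) but at 0.01 (SE 0.01) under total scaling, and xylanase at -0.15 (SE 0.06) but at 0.02 (SE 0.02). Glx, glyoxal oxidase, and ligninase stood at -0.09 (SE 0.07) and -0.08 (SE 0.17), and both at 0.09 under total scaling. Mannanase, of hemicellulose breakdown, stood at -0.10 (SE 0.06), against 0.21 (SE 0.08) under total scaling, where 91.1% of the difference in signal came from 1 probe of Opitutus terrae and the change without it was 0.02. That probe gave 220013 on N6 replicate 4 and 98235 to 122202 on the other N6 arrays, and 131963 on N9 replicate 4 and 223640 to 414379 on the other N9 arrays.

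Counts by list for N9 against N0 follow, where each count passing is adjusted over the list alone after quantile normalisation, and under total scaling 0 members of these lists passed. Here and below, that adjustment does not correct over the number of lists. The members of a list also share the shift of most families, so a whole list can pass with it. Starch had 5 of 6 families below N0 and 2 passing, pectin 9 of 10 and 0, hemicellulose 4 of 4 and 3, cellulose 4 of 4 and 3, and chitin 5 of 5 and 3. Lignin had 4 of 4 below and 2 passing, lignin-derived aromatic compounds 4 of 5 and 0, and protein and lipid degradation, whose members are cutinase, a fungal lipase and fungal phospholipases, 4 of 4 and 4. Over carbon degradation as a whole, 39 of 42 families lay below N0 (26 under total scaling), 25 at an unadjusted p under 0.05 (3 under total scaling) and 4 passing when adjusted over the list alone. The summed signal of carbon degradation differed by -0.18 (SE 0.07, limma adjusted p = 0.0984), against -0.00443 (SE 0.00865) under total scaling. Its share of the signal was 28.3% ± 0.19 at N0 and 28.2% ± 0.20 at N9 (SD, n = 4). Cellulose genes took 1.88% ± 0.041 at N0 and 1.81% ± 0.071 at N9, and lignin genes 1.27% ± 0.038 and 1.23% ± 0.028.

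**Figure D3:**
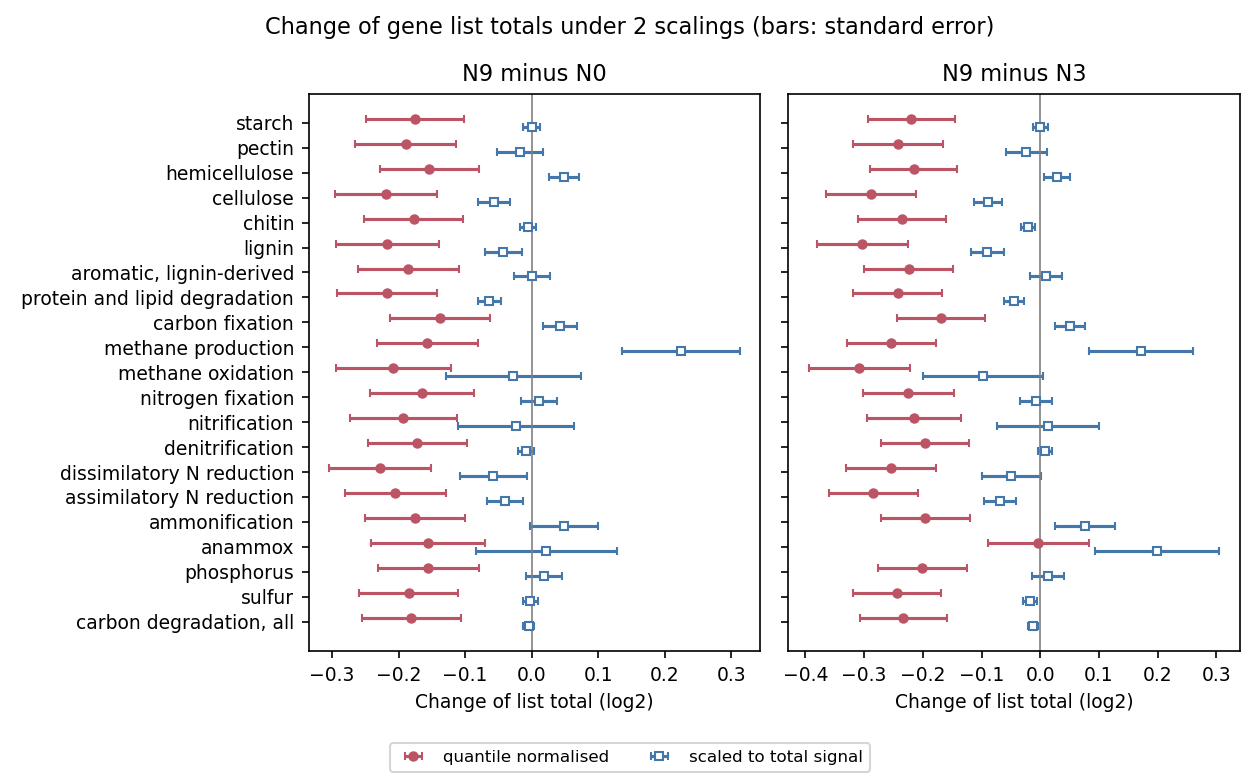
Change of each list total on the log2 scale for N9 minus N0 and N9 minus N3, with the standard error of the limma fit (4 arrays per level), after quantile normalisation and after scaling to total signal. For N9 minus N0 all 21 lists lie below 0 after quantile normalisation (from -0.23 to -0.14) and 13 under total scaling (from -0.06 to 0.22); under median scaling all 21 lie above 0.

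None of the named nitrogen, sulfur, phosphorus and one-carbon genes passed the test over all families either, and under median scaling they turned positive except amoA and phytase. The denitrification genes nirK and nirS, for nitrite reduction, stood at -0.21 (SE 0.08) and -0.22 (SE 0.08), nosZ, for nitrous oxide reduction, at -0.19 (SE 0.08), and narG, for nitrate reduction, at -0.14 (SE 0.05), against 0.01 (SE 0.02) under total scaling. NifH, for nitrogen fixation, stood at -0.17 (SE 0.08), against 0.01 (SE 0.03) under total scaling, and ureC, of urease, at -0.22 (SE 0.08). AmoA, for ammonia oxidation, stood at -0.25 (SE 0.17) and pmoA, for methane oxidation, at -0.25 (SE 0.12). Phytase, which frees phosphate from phytate, stood at -0.30 (SE 0.10, adjusted p = 0.0948, lower on 3 of 4 arrays), and the assimilatory sulfite reductase gene cysJ at -0.20 (SE 0.06). Gdh, glutamate dehydrogenase, stood at -0.06 (SE 0.05), against 0.23 (SE 0.09) under total scaling, where 97.3% of the difference came from 1 probe of Leifsonia xyli and the change without it was 0.00519. McrA, of methane production, stood at -0.16 (SE 0.08), against 0.22 (SE 0.09) under total scaling, where 1 probe of an uncultured archaeon differed by 97399 and the family by 83762, and the change without it was -0.06. On N6 replicate 4 these probes of gdh and mcrA gave 293053 and 192580, above the other N6 arrays, and on N9 replicate 4 they gave 133473 and 123253, below the other N9 arrays.

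Adjusted over the list alone, 5 of 5 denitrification families passed, as did 2 of 2 of dissimilatory nitrogen reduction, 0 of 4 of assimilatory nitrogen reduction, 1 of 1 of nitrogen fixation, 1 of 2 of ammonification and assimilation, 0 of 2 of nitrification and 0 of 2 of anammox. The counts were 7 of 14 for sulfur, 1 of 3 for phosphorus, 0 of 7 for carbon fixation, 0 of 1 for methane production and 0 of 2 for methane oxidation. All members of these lists lay below N0, while under total scaling the list-alone passes were mcrA, of methane production, and gdh, of ammonification and assimilation, both above N0. A list of 1 member gets no correction this way. NifH had an unadjusted limma p of 0.0457, or 0.133 adjusted over all families. Under total scaling mcrA had 0.0175 and gdh 0.0149 by the same test, and both 0.601 adjusted over all families. In the limma test 0 of 320 families passed, with 119 at an unadjusted p under 0.05, 24 under total scaling, 28 under median scaling and 25 as deposited. The levels did not overlap for 65 families, 20.3% against the 2.86% that chance gives for a single family. All 65 lay lower at N9, against 5 of 10 under total scaling (3.13%) and 0 of 13 under median scaling. Of the 21 list totals 0 passed (19 at an unadjusted p under 0.05, 4 under total scaling, smallest adjusted p 0.0972). The count of families was 116 without N9 replicate 4 and 115 without N6 replicate 4, and that of list totals 19 and 15.

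By source organism, summed fungal signal fell at N9 by 0.22 (SE 0.07, limma adjusted p = 0.0308, exact p = 0.0286), against -0.03 under total scaling (exact p = 0.114) and 0.06 under median scaling. Archaeal signal fell by 0.19 (SE 0.07, adjusted p = 0.0479, exact p = 0.0571), but stood at 0.02 under total scaling and 0.10 under median scaling. Bacterial signal stood at -0.17 (SE 0.07, adjusted p = 0.0745), against 0.00157 under total scaling. Fungal probes took 6.29% ± 0.078 of the signal at N0 and 6.15% ± 0.12 at N9, and archaeal probes 1.99% ± 0.029 and 2.01% ± 0.017 (SD, n = 4). The limma values share 1 estimate of the spread over 5 correlated sums, and the count of 2 became 0 without any 1 of N0 replicates 1, 3 and 4 or N9 replicates 1, 2 and 3, 1 without any N3 array or N6 replicate 1 or 2, and 4 without N6 replicate 4 or N9 replicate 4.

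Of 31276 single probes 18 passed for N9 against N0, 17 lower and 1 higher (4506 at an unadjusted p under 0.05). The median change of all tested probes was -0.33, with 23319 below 0, against -0.09 under total scaling, with 17969 below 0. The direction of the calls cannot be told apart from this shift. A nifH probe of an uncultured bacterium was higher by 1.99 (SE 0.35), and a nirK probe fell by 3.12 (SE 0.55). Others that fell were probes of the transketolase gene tktA of Burkholderia graminis (-2.24, SE 0.31), of the arabinofuranosidase gene ara of a Paenibacillus (-1.71, SE 0.28) and of nosZ of Pseudomonas fluorescens (-1.05). Under total scaling 0 passed (2432 at an unadjusted p under 0.05). Left out 1 at a time, 15 of the arrays changed the count to between 0 and 11 or to 104 without N9 replicate 4, and N6 replicate 4 to 678.

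N9 against N3 sets the highest rate against the lowest addition and held the most calls. Exoglucanase fell by 0.34 (SE 0.07, limma adjusted p = 0.0145, lower on 4 of 4 N9 arrays), or -0.10 relative to the median family shift of -0.24, and endoglucanase fell by 0.31 (SE 0.08, adjusted p = 0.0145, 4 of 4). Mnp fell by 0.44 (SE 0.14, adjusted p = 0.0294, 4 of 4), or -0.20 relative to the shift, and phenol oxidase by 0.31 (SE 0.08, adjusted p = 0.0147, 4 of 4). Pula, the debranching pullulanase of starch, fell by 0.35 (SE 0.10) and pectinase by 0.32 (SE 0.12), while acetylglucosaminidase and endochitinase, of chitin breakdown, both fell by 0.27 (SE 0.06 and 0.08) and xylanase by 0.24 (SE 0.06). Of these, mnp stood at -0.10 under median scaling, and the others stayed below 0 under total scaling but turned positive under median scaling. AmyA fell by 0.21 (SE 0.05), or 0.02 relative to the shift, and vanA, of vanillate degradation, by 0.23 (SE 0.07), and they turned to 0.00732 and 0.00654 under total scaling.

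In total 120 of 320 families fell at N9 against N3 and 0 rose (169 at an unadjusted p under 0.05), with a median change of -0.32 and a range of -1.50 to -0.16. Of these, 88 lay below the median shift, 106 were lower on 4 of 4 N9 arrays than the N3 mean, and 101 stayed below 0 under total scaling, where 37 had an unadjusted p under 0.05. The 120 were chosen as lower on these same arrays, so such counts follow largely from the choice. Of all 320 families, 297 lay below 0 after quantile normalisation and 192 under total scaling. By limma under total scaling, median scaling or as deposited 0 families passed (57, 85 and 51 at an unadjusted p under 0.05; smallest adjusted p 0.132 under total scaling). The levels did not overlap for 116 families, 36.3% against the 2.86% that chance gives for a single family. All 116 lay lower at N9, against 24 of 31 under total scaling (9.69%) and 2 of 50 under median scaling. The count was 187 without N9 replicate 4 and 181 without N6 replicate 4, and 25 to 73 without any 1 of the N3 arrays or of N9 replicates 1 to 3.

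Of the 42 carbon degradation families 27 fell at N9 against N3 and 30 passed when adjusted over the list alone (0 under total scaling, with 12 at an unadjusted p under 0.05). All 4 cellulose families fell, among them axe, an esterase of xylan side chains, and 2 of them passed under total scaling when adjusted over the list alone. The counts that fell were 6 of 10 for pectin, 3 of 6 for starch, 4 of 5 for chitin, 2 of 4 for lignin, 3 of 4 for hemicellulose, 3 of 4 for protein and lipid degradation and 2 of 5 for the list of lignin-derived aromatic compounds, where limeh acts on limonene and vanA on vanillate. Of the denitrification families 4 of 5 fell and of the sulfur families 8 of 14. Under total scaling the sulfur families dsrA (-0.10), dsrB (-0.12) and Sir (-0.18) passed when adjusted over the list alone, while sqr stood at 0.42. Of the list totals 19 of 21 fell, among them cellulose, by 0.29 (SE 0.08, adjusted p = 0.00704), lignin, by 0.30 (SE 0.08, adjusted p = 0.00704), and carbon degradation, by 0.23 (SE 0.07, adjusted p = 0.0138). Under total scaling 0 passed (4 at an unadjusted p under 0.05), with cellulose at -0.09 (SE 0.02), lignin at -0.09 (SE 0.03) and carbon degradation at -0.01 (SE 0.01), and under median scaling these 3 turned to 0.06, 0.05 and 0.13. The limma values of the 21 list totals largely share 1 estimate of the spread over correlated sums, of which carbon degradation joins several. An exact permutation test of each total gave 0. Without N9 replicate 1 the count of list totals was 3, and without N9 replicate 2 it was 5.

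Fungal signal fell at N9 against N3 by 0.31 (SE 0.07, limma adjusted p = 0.000442, exact p = 0.0286) and by 0.08 under total scaling (adjusted p = 0.0477, exact p = 0.0286), but stood at 0.06 under median scaling. It was the only organism total of 5 that passed after both quantile normalisation and total scaling, since bacterial, other eukaryotic and unassigned signal fell after quantile normalisation and stood above 0 under total scaling. Under median scaling 4 organism totals passed in the other direction, at 0.14 for archaea, 0.15 for bacteria, 0.18 for other eukaryotes and 0.19 for unassigned probes. The log2 ratio of fungal to bacterial signal differed by -0.09 (95% interval -0.137 to -0.0396, exact p = 0.0286, adjusted 0.286), lower on all 4 N9 arrays than the N3 mean. The count of 5 organism totals was 2 without N9 replicate 1 and 3 without N3 replicate 3, N3 replicate 4, N9 replicate 2 or N9 replicate 3. Of 31172 probes 1119 fell and 19 rose (7111 at an unadjusted p under 0.05), against 0 under total scaling (4143 at an unadjusted p under 0.05). The median change of all tested probes was -0.40, with 22989 below 0, against -0.15 under total scaling, with 18459 below 0. The 1138 became 0 without N3 replicate 1, N3 replicate 3 or N9 replicate 3, 4 without N3 replicate 2 and 5305 without N6 replicate 4, and lay between 364 and 672 without N0 replicate 1, N3 replicate 4, N6 replicate 2 or N9 replicate 2.

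**Figure D4:**
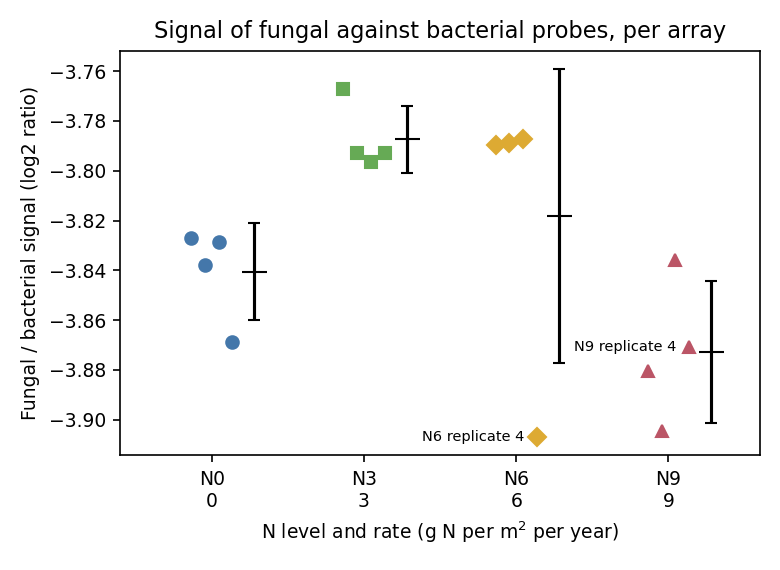
Log2 ratio of the summed signal of fungal probes to that of bacterial probes on each array, by nitrogen level with its rate in g of nitrogen per square metre per year. Points are arrays and the bars beside them give the mean and SD of 4 arrays; the means are -3.84 at N0, -3.79 at N3, -3.82 at N6 and -3.87 at N9.

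The remaining comparisons concern the steps between levels and the trend over rates. Between N9 and N6, fungal signal fell by 0.24 (SE 0.07, limma adjusted p = 0.00524, exact p = 0.0857), the lignin list by 0.24 (SE 0.08, adjusted p = 0.0145), cellulose by 0.23 (SE 0.08, adjusted p = 0.0162) and carbon degradation by 0.19 (SE 0.07, adjusted p = 0.0337), among 12 list totals of 21 and 5 organism totals of 5. Under total scaling 0 list totals and 0 organism totals passed (4 and 1 at an unadjusted p under 0.05), with lignin at -0.07 (SE 0.03) and cellulose at -0.07 (SE 0.02), and under median scaling fungi, lignin, cellulose and carbon degradation turned to 0.04, 0.02, 0.02 and 0.08. In limma 0 families passed (106 at an unadjusted p under 0.05, and 20 under total scaling), with 184 called without N6 replicate 4, 127 without N9 replicate 4 and 1 without N9 replicate 3. For probes, 56 fell and 1 rose (0 under total scaling), while the median change of all tested probes was -0.28, against -0.07 under total scaling. The list count was 0 to 7 without any 1 of N3 replicates 2 to 4, N6 replicates 1 to 3 or N9 replicates 1 to 3, and 19 without N6 replicate 4. Exact permutation tests gave 0 list totals, and the spread shared over correlated sums limits these limma values too. Leaving out any array changed the probe count, to between 0 and 31, to 265 without N9 replicate 4 or to 2301 without N6 replicate 4. The organism count became 1 to 3 without any 1 array other than N6 replicate 4 and N9 replicate 4. Between N6 and N3, 0 families, 0 probes, 0 list totals and 0 organism totals passed in limma (1, 907, 0 and 0 at an unadjusted p under 0.05), and 1 list total passed without N6 replicate 3 or N9 replicate 4. Any difference among the 4 levels gave 0 families (101 at an unadjusted p under 0.05), and 135 without N6 replicate 4 or 111 without N9 replicate 4. The linear trend over nitrogen rate gave 0 families (117 at an unadjusted p under 0.05), with 294 slopes below 0, and 1 without N9 replicate 4.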

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

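The tests of explanations and the counts over other groupings of the arrays in this part were chosen after the results were seen. Of 352 groups of 4 arrays checked for 1 array far from the other 3, 40 held one, where chance flags about 1 in 20 groups, or 17.6; the groups are not independent of each other. N6 replicate 4 accounts for 33 of the 40 and N9 replicate 4 for 4. On N6 replicate 4 the Shannon index was 9.44 and the mean correlation with the other arrays 0.728, against 0.889 to 0.903 for the other N6 arrays. Its summed signals, on the log2 scale, lay below those of the other 3 N6 arrays for pectin (21.71), hemicellulose (22.18), cellulose (21.12), lignin (20.51), nitrogen fixation (21.06), denitrification (22.89), dissimilatory nitrogen reduction (19.12), assimilatory nitrogen reduction (19.94) and ammonification (21.28), and for archaea (21.16), fungi (22.81) and other eukaryotes (20.02). The same held for the carbon genes endochitinase (19.69), endoglucanase (19.24), mannanase (19.66), mnp (17.19), pectinase (18.91), phenol oxidase (20.07), the fungal glucose oxidase (16.47) and codh (17.15). It also held for the nitrogen and sulfur genes narG (21.77), nifH (21.06), nirS (20.08), nosZ (20.62), ureC (20.75), dsrA (20.74), cysJ (20.48) and sqr (19.07), and for fcba (14.70), cbea (13.64) and phta (17.07), which act on organic pollutants. All these sums were taken after quantile normalisation, which lowers them on arrays with fewer detected probes. N6 replicate 4 had 32574 probes, against 37931 to 39180 on the other N6 arrays. The flags on its sums and its Shannon index therefore cannot be told apart from its lower probe number.

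On N9 replicate 4 the array stood apart from the other 3 N9 arrays with a lower value for nbzc (13.61) and with higher values for lmo (14.89), ara (20.90) and phytase (19.61). It had 36367 probes detected, against 30885 to 32490 on the other N9 arrays, which raises its sums after quantile normalisation. The ammonification list was low on N0 replicate 2 (21.60), the aromatic peroxygenase on N3 replicate 3 (12.28) and mannanase on N3 replicate 4 (19.83).

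N6 replicate 4 and N9 replicate 4 correlate least with the other arrays. The low correlations were not confined to the brightest probes. Without the 639 probes among the brightest 1% of any array the mean correlations of these arrays were 0.689 and 0.724, against 0.796 to 0.887 for the other 14. The correlations were taken on log2 signals after quantile normalisation, where a few probes weigh little. The check could therefore hardly show an effect of bright probes, and it does not exclude one. The mean correlation of N6 replicate 4 was higher by 0.0472 with the N9 arrays than with the other N6 arrays, as a swap of labels with N9 replicate 4 could give, but much of this came from its correlation of 0.832 with that array, and with the other N9 arrays it was 0.742, against 0.717. N9 replicate 4 was the only N9 array closest to N6 of all levels (all 4 were closer to N6 than to N9), yet after an exchange it would correlate at 0.789 with the other N6 arrays, against 0.929 to 0.957 among those, and N6 replicate 4 would lie below the 0.787 to 0.855 of the other N9 arrays. Other values went with an exchange. Probes detected numbered 32574 on N6 replicate 4 and 36367 on N9 replicate 4, and the bright gdh probe gave 293053 and 133473. Whether the labels were exchanged cannot be told apart from 2 poorly correlated arrays, and no biological explanation was tested.

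Fewer probes were detected at N9 than at N0. The 702 probes seen on 4 of 4 N0 arrays and on 0 of 4 N9 arrays had a median percentile of 4.18 by N0 signal, with an upper quartile of 8.49, so dim probes that fell below the detection limit may be the larger part. The phylum of the source organism explained 2.69% of the deviance of probe loss (permutation p = 0.000999, the smallest these permutations can give), with 0.577% lost of Actinobacteria and 4.81% of Chloroflexi; a loss of particular phyla cannot be told apart from differences in brightness between their probes. A loss of rare genes under added nitrogen, which the design allows, stays open and was not tested, and the detection rule of the authors is not known.

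Gene families were lower at N9 than at N3. Of the 120 families called, 101 stayed below 0 under total scaling, as did 192 of all 320, but the 120 had been chosen as lower on the same arrays. The call of 120 became 0 under total scaling, as an array-wide shift would give, and the median family change moved from -0.24 to -0.03. This is in line with a shift that follows the number of probes detected, whose log2 ratio was -0.22. A change of particular families beneath that shift, such as mnp at -0.24 under total scaling, stays open, as does a response to nitrogen itself, which was not tested apart from the shift.

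Other groupings of the same 8 arrays, 35 in number with the real one, were used to ask whether chance could give as many calls. A count of 1 of 35 is the smallest that these groupings can give, each count was read without correction for the others, and all were taken after quantile normalisation, where the calls depend on scaling. For N9 against N3 the real grouping gave the most calls for families (1 of 35 with as many, 120, highest other 90). It also did for list totals (1 of 35, 19, highest other 13) and organism totals (1 of 35, 5, highest other 3). Both are sums of the same signals as the families. For probes it did not (2 of 35, 1138, highest other 1247). For N9 against N0 it did for probes (1 of 35, 18, highest other 0). For organism totals it did not (3 of 35, 2, highest other 3). For N9 against N6 it did not for list totals (3 of 35, 12, highest other 21). The same held for organism totals (3 of 35, 5, highest other 5) and probes (5 of 35, 57, highest other 7500). At the smallest share possible and without correction, these counts do not exclude chance.

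Where the real count was 0, every grouping gives as many (35 of 35), so the groupings say nothing about chance. This holds for families (highest other 111) and list totals (highest other 14) of N9 against N0, for families of N9 against N6 (highest other 196), and for N3 against N0, N6 against N0 and N6 against N3. For those 3 comparisons the highest other counts were 0, 1 and 0 for families, 1, 1 and 1 for list totals, 0, 4 and 1 for organism totals and 0, 0 and 1 for probes, in that order. The same holds for any difference among levels (0, highest other 124) and for the trend (0, highest other 198), each with 100 of 100 groupings. Groupings that call many times the real count point to a structure of the samples that the levels do not follow. The 196 families between N9 and N6 came when N6 replicate 4 and N9 replicate 4 changed places. That grouping sets the arrays with 30885 to 32574 probes detected against those with 36367 to 39180. After quantile normalisation sums are lower on arrays with fewer detected probes, so the 196 go with the number detected.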

How the results depend on the processing

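The settings that leave out both N6 replicate 4 and N9 replicate 4 were chosen after the data had been seen. The count of 0 families for N3 against N0, N6 against N0 and N6 against N3 (limma, 2, 1 and 1 at an unadjusted p under 0.05) held under every alternative run. Probe numbers and the Shannon index did not pass under any alternative either, but with a smallest exact p of 0.0286 for 4 against 4 arrays they could hardly do so, and this says nothing about stability. Without a probe filter all 306 results held, as did the 4 with a stricter rule of detection. Of 317 results, 279 held under total scaling, 278 under median scaling and 279 as deposited. A result that passed in neither setting counts as held even where its direction turned. All 21 list totals of N9 against N0 turned above 0 under median scaling and still count as held. Such counts therefore say little about the stability of directions. For families of at least 10 probes 179 of 180 held, and for list values taken as means over families 74 of 75. Quantile normalisation gives lower sums to arrays with fewer detected probes, and this construction separates it from total scaling. Total and median scaling also differed, with a median family change of -0.03 against 0.11 for N9 against N3. The cause of that gap and of the other changes was not tested. Signal over background could not be assessed, since the files hold no background values, so the limit of detection is not known.

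Under total scaling 0 families passed for N9 against N3 in limma (57 at an unadjusted p under 0.05), and amyA, ara and vanA turned to 0.00732, 9.09e-05 and 0.00654. Probe counts became 1 for N3 against N0, 3 for N6 against N0 and 0 for N9 against N0, N3 and N6. List totals gave 0 for N9 against N3 and 0 against N6, with carbon degradation at -0.0130 and -0.0109. Organism totals gave 0 for N9 against N0, 1 against N3 and 0 against N6. Archaea turned to 0.0163 against N0, and against N3 bacteria turned to 0.00511, other eukaryotes to 0.0357 and unassigned probes to 0.0502.

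As deposited, limma gave 0 families for N9 against N3 (51 at an unadjusted p under 0.05), and probe counts of 1, 3, 0, 0 and 0 in the order used for total scaling. List totals gave 0 for N9 against N3 and 0 against N6, with carbon degradation at -0.0280 and -0.0220. Organism totals gave 0 against N0, 1 against N3 and 0 against N6, with archaea at 0.00201 against N0, and other eukaryotes at 0.0207 and unassigned probes at 0.0351 against N3.

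Under median scaling 0 families passed for N9 against N3 in limma (85 at an unadjusted p under 0.05), and probe counts were 1, 3, 0, 0 and 0 in the same order. Carbon degradation families that turned positive for N9 against N3 included acetylglucosaminidase (0.0947), amyA (0.15), ara (0.14), cellobiase (0.11), endochitinase (0.10), endoglucanase (0.0237) and exoglucanase (0.00611). Others were pectinase (0.0248), phenol oxidase (0.0538), pula (0.00201), vanA (0.15), xylA (0.11) and xylanase (0.12). The turn was not limited to them, with mcrA at 0.32, nifH at 0.14 and the median of all families at 0.11. List totals gave 0 for N9 against N3, with cellulose at 0.0557, lignin at 0.0545 and carbon degradation at 0.13, and 0 against N6, with values of 0.0226, 0.0192 and 0.0809. Organism totals gave 1 for N9 against N0, where archaea turned to 0.10, fungi to 0.0575 and unassigned probes to 0.17. Against N6 they gave 0, with fungi at 0.0402. Against N3 archaea turned to 0.14, bacteria to 0.15, fungi to 0.0643, other eukaryotes to 0.18 and unassigned probes to 0.19.

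With only probes detected on all 16 arrays, 78 families passed for N9 against N3. Probes gave 0 for N9 against N0, 28 against N3 and 0 against N6, and the cause was not tested. Organism totals gave 1 for N9 against N0, 3 against N3 and 3 against N6. With family values as mean log2 signals, 2 families passed for N9 against N0, 213 against N3 and 1 for any difference, and the cause was not tested. With only the compared levels in the fit, 0 probes passed for N9 against N0, 0 against N3 and 0 against N6, with fewer arrays to estimate the spread. With missing signals at the array minimum, probe counts were 5 for N3 against N0, 9 for N6 against N0, 224 for N9 against N0, 3387 against N3 and 19 against N6, and the cause was not tested.

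The share of variation in composition that the level accounted for became 0.439 (permutation p = 0.01) with Jaccard distances and 0.372 (permutation p = 0.015) with log2 signals, and the cause was not tested. With exact permutation tests, 0 list totals passed for N9 against N3 and 0 against N6, and carbon degradation, at -0.23 and -0.19, no longer passed (adjusted p = 0.129 and 0.164), since the smallest exact p leaves little room for correction. With list values as mean log2 signals, 16 list totals passed for N9 against N0 and 19 against N6, and carbon degradation fell by 0.30 against N0 (adjusted p = 0.0478).

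The replicate number as a block left 303 of 313 results on their side of the threshold. It gave probe counts of 1 for N9 against N0 and 125 against N6, and organism counts of 0 against N0, 3 against N3 and 1 against N6. The labels give the numbers no shared plot, batch or day, and the samples were not taken as paired, since only 17 of 24 pairs of arrays with the same number had a correlation over 0.1 and the lowest was -0.258. The median correlation was 0.164 for arrays of the same number and -0.0486 for other arrays, and 6 of 16 arrays correlated best with an array of their own number, so some structure by number cannot be ruled out.

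Without N6 replicate 4 and N9 replicate 4 the share of variation in composition was 0.363 (permutation p = 0.015). Family counts were 197 for N9 against N0, 232 against N3, 224 against N6, 203 for any difference and 1 for the trend, and probe counts 2332, 5739 and 4419 for N9 against N0, N3 and N6. List totals gave 1 for N3 against N0, 3 for N6 against N0, 21 for N9 against N0 and 21 against N6, with pectin turned to 0.0890 for N6 against N0 and carbon degradation at -0.22 for N9 against N0, past the threshold. Organism totals gave 1 for N3 against N0, 3 for N6 against N0 and 5 for N9 against N0, and other eukaryotes turned to 0.0790 for N6 against N0.

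Total scaling without these arrays gave 15 families for N9 against N0, 62 against N3, 36 against N6, 30 for any difference and 1 for the trend. For N9 against N0 gdh turned to 0.34, mannanase to 0.31 and mcrA to 0.29, and against N3 amyA turned to 0.0210, mannanase to 0.32 and vanA to 0.00532. Probe counts were 1 for N3 against N0, 5 for N6 against N0 and 153, 113 and 135 for N9 against N0, N3 and N6. List totals gave 4 for N9 against N3 and 4 against N6, with carbon degradation at -0.00745 and -0.00703. Organism totals gave 0 for N9 against N0, with archaea at 0.0224, and 2 against N3 and 2 against N6. Against N3 archaea turned to 0.00325, bacteria to 0.00527, other eukaryotes to 0.0482 and unassigned probes to 0.0583.

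With each array left out in turn, family counts ranged from 0 to 116 for N9 against N0, 25 (without N3 replicate 3) to 187 (without N9 replicate 4) against N3, 0 to 184 against N6, 0 to 135 for any difference and 0 to 1 for the trend. Probe counts ranged from 0 to 1 for N3 against N0, 0 to 3 for N6 against N0, 0 to 678 for N9 against N0, 0 to 5305 against N3 and 0 to 2301 against N6, and those for N9 were highest without N6 replicate 4. Counts of list totals ranged from 0 to 19 for N9 against N0, 3 to 20 against N3 and 0 to 19 against N6, and from 0 to 1 for N6 against N3. Carbon degradation ranged from 0.0297 to 0.0672 for N3 against N0, -0.0239 to 0.0680 for N6 against N0, -0.22 to -0.15 for N9 against N0, -0.28 to -0.21 against N3 and -0.25 to -0.16 against N6. Organism counts ranged from 0 to 4 for N9 against N0, 2 to 5 against N3 and 1 to 5 against N6. The difference in probes detected ranged from 525 to 1634 for N3 against N0, -675 to 1527 for N6 against N0 and -5337 to -3509 for N9 against N0, and the share of variation in composition from 0.196 to 0.289. Why single arrays carry this weight was not tested.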

Other observations

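The tests and settings in this part, total scaling without N6 replicate 4 and N9 replicate 4 and the ratios of gene groups, were chosen after the data had been seen. Without these arrays and under total scaling, where each family is read as a share of the array's signal, 15 families passed for N9 against N0 (limma, 80 at an unadjusted p under 0.05), 7 higher and 8 lower. Phytase, which frees phosphate from phytate, fell by 0.18 (SE 0.04, adjusted p = 0.0118), mnp, the manganese peroxidase of lignin breakdown, by 0.25 (SE 0.07, adjusted p = 0.0433), and the fungal phospholipase D by 0.34. Gdh, glutamate dehydrogenase, rose by 0.34 (SE 0.05, adjusted p = 0.00371), mannanase by 0.31, mcrA by 0.29 and ccmM, of the carboxysome shell, by 0.43. Without the single bright probe described for each, in the same setting, gdh stood at 0.0540, mannanase at 0.0570 and mcrA at -0.10. For N9 against N3, 62 families passed, 26 higher and 36 lower, among them 2 higher and 7 lower of the 42 carbon degradation families. Those lower included mnp, pula, phenol oxidase and endoglucanase, and those higher were mannanase, at 0.32 but 0.0744 without its bright probe, and camdcab. For N3 against N0 and N6 against N0 the counts were 0 (17 and 4 at an unadjusted p under 0.05). Removing arrays for their poor correlation shrinks the spread between the rest, so these counts are not independent evidence.

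The deposited table assigns each probe to a category of its own. The category that holds genes used as phylogenetic markers, with 237 probes and 0.357% of the signal, differed by -0.30 between N9 and N0 (limma adjusted p = 0.00162 among the categories), against -0.13 (adjusted p = 0.194) under total scaling. Among the finer subcategories, where the same probes form one, the change did not pass (adjusted p = 0.15, and 0.535 under total scaling), so the call depends on which sums share the fit. Carbon cycling as a category differed by -0.17 (adjusted p = 0.0727). Single bright probes changed several families under total scaling. The Leifsonia xyli probe of gdh gave 105740 ± 12775 at N0 and 256182 ± 103931 at N9 (SD, n = 4), the Opitutus terrae probe of mannanase 138927 ± 33592 and 279002 ± 125837, and the mcrA probe of an uncultured archaeon 134168 ± 40284 and 231567 ± 93555. Probes detected on all 12 arrays of the other levels and on no N9 array numbered 47.

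Ratios of gene groups within an array do not depend on the scaling of arrays by a single factor, and 5 hypotheses on them were tested between N9 and N0 with two-sided exact permutation tests on 4 against 4 arrays. Fungal against bacterial signal differed by -0.0323 (log2), and its 95% interval, -0.0776 to 0.0328, lay within 0.1 of 0. That interval is 1 of 5 without correction, and the bound of 0.1 was set after the values were seen, so a larger shift is not excluded. The value was -0.0488 after quantile normalisation, -0.0218 without N9 replicate 2 and -0.0447 without N9 replicate 3. The other ratios stay undecided, since their intervals reach beyond 0.1 and none passed the correction. Lignin against starch genes differed by -0.0422 (interval -0.113 to 0.0479), cellulose against hemicellulose by -0.105 (-0.293 to 0.0593), nosZ against nirK and nirS together, nitrous oxide against nitrite reduction, by 0.0156 (-0.121 to 0.188), and mcrA against pmoA, methane production against oxidation, by 0.295 (-0.401 to 0.979). The cellulose to hemicellulose value (exact p = 0.171) was -0.0604 without N9 replicate 1, -0.142 without N9 replicate 4, -0.0654 after quantile normalisation and -0.0688 without the Opitutus terrae probe of mannanase. The mcrA to pmoA value was 0.148 without N9 replicate 1, 0.474 without N9 replicate 4, 0.0958 after quantile normalisation and 0.0135 without its bright probe, so it rests on that probe. The value for nosZ was -0.00449 without N0 replicate 1 and 0.0416 without N0 replicate 4, and that for lignin to starch -0.0278 without N9 replicate 1 and -0.0631 without N9 replicate 4.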
